A study of Mus musculus with 10 samples.

How the data were processed

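The deposited tables hold 1 value per gene and library for 24421 genes in 10 libraries, in 3 tables: the Klf5 knockdown, the Tfap2c knockdown, and the motif knockouts together with the control. The values are log2 per the deposited tables' names, and their exact zeros put the added constant at 1. The kind of abundance is not named, and the linear values of a library sum to between 388454 and 498621 units, so they are not a complete TPM column. Per the submitters' processing notes the tools were HISAT2 2.1.0, SAMtools 1.7, StringTie 1.3.4 and Cufflinks with the mm10 build. Per the labels' protocols, 8-cell embryos of BDF1 genotype were freed of zona and polar bodies, and total RNA libraries were made with random primers and depleted of ribosomal cDNA after amplification. Read counts were not analysed here, so depth is unknown. An added constant of 1 understates changes of genes with low values. An exact 0 can be a failed estimate: Gapdh is listed at 0 to 0.81 log2 units in these libraries, and 26.0% to 34.5% of values are 0. Rn45s, the ribosomal RNA precursor, holds 5.61% to 8.07% of the linear sums.

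The groups, comparisons, tests, thresholds, gene lists, the rule for naming genes and most alternatives were set before the data were examined. Genes with at least 1 linear unit in at least 2 libraries were tested on the deposited log2 values with limma 3.58.1 in R 4.3.3 (eBayes with trend), and called at a Benjamini-Hochberg adjusted p under 0.05. All gene p-values in the text are from limma unless another test is named. The plan was to fit each table alone, with the control beside each knockdown. The control libraries stand only in the motif knockout table, so the knockdown comparisons were fitted across tables, on all 10 libraries (11195 genes), and rest on values that may have been scaled apart. The motif knockouts were fitted in their own table of 6 libraries (10920 genes). With 2 libraries a group, p-values measure only the spread between these libraries. The labels do not say whether these come from separate embryo pools, so the spread may be technical.

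Of 23 gene lists, 21 had tested members; the spermatid and the mitochondrially encoded lists had 0. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. With an estimated correlation camera rests on the residual degrees of freedom, 5 in the knockdown and 3 in the motif knockout fits. The preset form does not rest on these few, so their p-values differ in power. A miss with the estimated form does not decide whether gene correlation accounts for a list's result. Lists overlap, as with Klf2, Klf4 and Klf17 in both the pluripotency and the Klf family list. Counts adjusted over the list alone apply the adjustment to the genes of 1 list. Positions are from GENCODE M21, where 23334 symbols have 1 gene model. Genes named are the 4 targets; the 8 largest rises and 8 largest falls among called genes whose libraries do not overlap between groups and whose higher group mean is at least 10 linear units (5 each way for the 2 direct comparisons), leaving out symbols that start with Gm and a digit, end in Rik or contain -ps; and up to 4 members with the lowest p of each list that passed camera or had at least 3 called members. With 2 libraries against 2, complete separation of the libraries in 1 given direction comes about by chance in 1 of 6 orders. Some of the genes this rule names are not reported here. Neighbours of Arpc1b and Cdx2 are the 5 genes on each side.

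The fits were tested on simulated data with 200 changed genes per comparison. At a log2 change of 1 they recovered 87% for the Klf5 knockdown, 81% for the Tfap2c knockdown, 87% for Arpc1bE_CdxE1, 82% for CdxE2, 81% between the knockouts and 89% between the knockdowns; at 2 they recovered 99% to 100%. Of the calls 3.23% to 5.73% were false. The shifted list passed camera in all 6 comparisons, and 0 of 20 unshifted lists did in each. The simulated spread was independent between genes and held no shift of whole libraries. So these shares do not cover lists of correlated genes or a shift such as that of the motif knockouts. Correlations and covariances of fold changes between comparisons were set beside 100 simulated draws of unchanged groups with shared controls.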

Results

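RNA was measured by total RNA sequencing in 10 libraries of mouse embryos at the 8-cell stage, in 5 groups of 2 libraries. The groups are a control, a knockdown of Klf5 (siKlf5), a knockdown of Tfap2c (siTfap2c), and a pair of knockouts of Tfap2c motifs in the genome, named Arpc1bE_CdxE1_KO and CdxE2_KO. Tfap2c is a transcription factor of the AP-2 family and Klf5 one of the Krüppel-like family. Cdx2 encodes a transcription factor of the trophectoderm, the outer lineage of the blastocyst, and Arpc1b a subunit of the Arp2/3 complex, which starts branched actin filaments. The positions of the deleted motifs were not among the labels. The values are gene abundances on a log2(value + 1) scale, and no read counts were given, so the sequencing depth is unknown. The abundances of a library added up to between 388454 and 395401 linear units in the control and knockdown libraries and to between 478651 and 498621 in the 4 motif knockout libraries.

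The first question was what became of the targeted genes, given here by GENCODE position on mm10. Klf5 (chromosome 14, 99298691 to 99315036) stood at 7.16 ± 0.04 log2 units in control (SD, n = 2) and at 4.27 ± 0.14 in its own knockdown, a log2 fold change of -2.90 (SE 0.10, adjusted p = 1.7e-06). Tfap2c (chromosome 2, 172549593 to 172558622) stood at 6.61 ± 0.0043 in control and at 4.01 ± 0.11 in its knockdown, where the log2 fold change was -2.60 (SE 0.09, adjusted p = 2.4e-07). Klf5 also fell in the Tfap2c knockdown, to 5.38 ± 0.09 (log2 fold change -1.78, adjusted p = 4.7e-06), while Tfap2c in the Klf5 knockdown differed from control by -0.07 (adjusted p = 0.70). Cdx2 (chromosome 5, 147300805 to 147307270) stood at 2.41 ± 0.09 in control and fell in the Tfap2c knockdown, to 0.40 ± 0.24 (log2 fold change -2.02, adjusted p = 0.00033). In the Klf5 knockdown Cdx2 was called lower, at 1.19 ± 0.05 (log2 fold change -1.23, adjusted p = 0.017), but this call was lost without any 1 of its 4 libraries. The adjusted p was then 0.089 without Klf5 knockdown replicate 1, 0.088 without replicate 2, 0.083 without control replicate 1 and 0.10 without control replicate 2. Arpc1b (chromosome 5, 145114215 to 145130705) fell in the Tfap2c knockdown, from 4.59 ± 0.16 to 1.25 ± 0.02 (log2 fold change -3.34, SE 0.11, adjusted p = 2.1e-07). In the Klf5 knockdown it differed by -0.35 (adjusted p = 0.095).

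**Figure D1:**
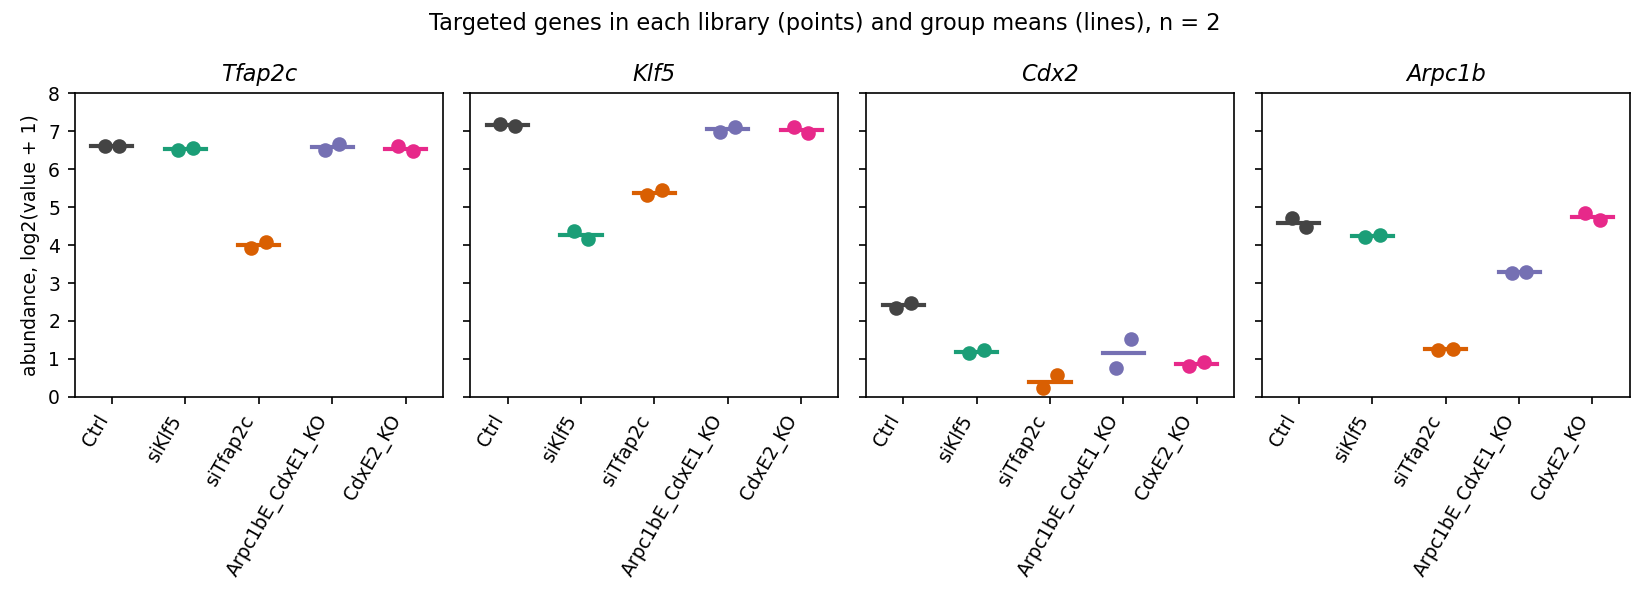
Abundance of the 4 targeted genes on the log2(value + 1) scale in each library (points) with group means (lines), for the 5 groups with n = 2. Tfap2c is low in siTfap2c alone, Klf5 in siKlf5 (4.27) and siTfap2c (5.38), Cdx2 lies below control (2.41) in the other groups, and Arpc1b is at 1.25 in siTfap2c and 3.29 in Arpc1bE_CdxE1_KO against 4.59 in control.

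The comparison of the Klf5 knockdown with control asks which 8-cell transcripts depend on Klf5. Besides Klf5 itself, Actn1, which cross-links actin filaments, had a log2 fold change of -1.82 (adjusted p = 1.6e-05) and Lasp1, an actin-binding adaptor, one of -1.81 (adjusted p = 0.00079). Polr2d, a subunit of RNA polymerase II, fell by 1.76 on the log2 scale, Serpinb6a, a protease inhibitor, by 1.72, Grb7, an adaptor of receptor kinases, by 1.56, Hapln4, a hyaluronan link protein, by 1.55 and Anpep, a cell surface aminopeptidase, by 1.54. The rises were smaller. P4ha2, a collagen prolyl hydroxylase, rose by 0.91 and Gyk, glycerol kinase, by 0.85. Btg3 (1.10), Csrnp3 (0.90), Zfp367 (0.90), Cited2, a transcriptional coregulator (0.88), Gdf11, a ligand of the TGF-beta family (0.85) and Dusp16, a MAP kinase phosphatase (0.83) were also called higher. In all, 842 of 11195 genes changed by limma, 252 up and 590 down, and 116 of them changed at least 2-fold, 17 up and 99 down. The share of higher genes moved from 29.9% to 46.2% when libraries were centred on their medians (379 up, 441 down). The count depended on each library: it was 317 without Klf5 knockdown replicate 1, 229 without replicate 2, 211 without control replicate 1 and 232 without control replicate 2, and 507 without the filter on low values. Of the 53 named genes called in this comparison, 24 kept their call without each library in turn. Of the others, 18 lost it without Klf5 knockdown replicate 1, 24 without replicate 2, 22 without control replicate 1 and 23 without control replicate 2. Among the rises above, P4ha2 and Gyk kept it in all 4, and Btg3, Csrnp3, Zfp367, Cited2, Gdf11 and Dusp16 did not (highest adjusted p 0.081, 0.061, 0.072, 0.18, 0.051 and 0.054).

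Several of the gene lists fixed beforehand lay lower in the Klf5 knockdown. In the list of the Arp2/3 complex and actin regulation, 9 of 29 tested genes fell and 0 rose (14 fell adjusted over the list alone), among them Rhoa, a GTPase that organises actin (-0.59), and the actins Actb (-0.56) and Actg1 (-0.72). The camera adjusted p of these genes was 3.1e-05, and the adjusted p = 0.068 with an estimated correlation. In the trophectoderm program 8 of 19 fell and 1 rose (9 and 1 adjusted over the list alone), with Hand1, a transcription factor of trophoblast, at -0.72, the keratin Krt8 at -1.44 and the endocytic receptor Lrp2 as the riser at 0.83. Camera gave these genes an adjusted p of 0.0033, and the adjusted p = 0.26 with an estimated correlation. Among pluripotency and inner cell mass genes 5 of 25 fell and 2 rose (7 and 2 adjusted over the list alone). Tdgf1, a co-receptor of Nodal, changed by -0.92, Tfcp2l1 by -1.32 and the nuclear receptor Nr5a2 by -0.47, and Klf2 by 0.52. The list's camera adjusted p was 0.0060, and the adjusted p = 0.17 with an estimated correlation. Of 26 cell polarity and junction genes 6 fell and 1 rose (8 and 1 adjusted over the list alone), led by Pard6b, a scaffold of the apical polarity complex (-1.02), with E-cadherin, Cdh1, at -0.54. By camera the list's adjusted p was 0.0033, and the adjusted p = 0.33 with an estimated correlation. In the Klf family 3 of 12 fell and 2 rose (4 and 2 adjusted over the list alone); Klf5 itself and Klf8 (-1.26) fell and Klf2 rose. For this list camera gave an adjusted p of 0.0088, and the adjusted p = 0.37 with an estimated correlation. Since the list holds Klf5, the gene knocked down, part of this result was fixed by the knockdown. The list was not tested without Klf5. Of 64 replication-dependent histone genes 8 fell and 0 rose (10 fell adjusted over the list alone), such as Hist1h2bm at -0.77 and Hist1h2bc at -0.65. The list's camera adjusted p was 0.0068, and the adjusted p = 0.81 with an estimated correlation. The calls of Krt8, Lrp2, Klf2 and Cdh1 were lost without 1 or more libraries (highest adjusted p 0.066, 0.096, 0.12 and 0.052), while the list calls held without each of the 4 libraries.

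Higher in the Klf5 knockdown were the cytosolic ribosomal proteins as a list (camera adjusted p = 1.8e-06, and adjusted p = 0.73 with an estimated correlation), although 2 of 86 rose, Rpl19 (0.67) and Rpl14 (0.24), and 1 adjusted over the list alone. In heat shock and integrated stress response genes 3 of 24 rose and 1 fell (4 and 1 adjusted over the list alone): Hspa5, the chaperone of the endoplasmic reticulum, changed by 0.71, Hspa1b by 0.63 and Hsph1 by 0.31, and the co-chaperone Bag3 by -1.16. By camera the list's adjusted p was 0.0079, and the adjusted p = 0.26 with an estimated correlation. The p53 response missed the threshold (3 of 26 rose and 2 fell, 4 and 2 adjusted over the list alone, camera adjusted p = 0.050, and 0.0097 without Klf5 knockdown replicate 2 and 0.049 with the replicate block, where it passed, against an adjusted p = 0.73 with an estimated correlation); Ddit4l (0.70), Polk (0.72) and Ei24 (0.41) rose and Perp fell (-1.02). In the Hippo pathway 2 of 23 rose and 2 fell (2 and 3 adjusted over the list alone), with Amotl1 at 1.05 and Cyr61 at 0.68 against Tead4 at -0.40 and Amotl2 at -0.71 (camera adjusted p = 0.998). Each of Rpl19, Rpl14, Hspa1b, Hsph1, Ddit4l, Polk, Ei24, Perp, Amotl1, Cyr61, Tead4 and Amotl2 lost its call without at least 1 library, with highest adjusted p from 0.061 for Amotl1 to 0.27 for Hsph1. The other lists did not pass. Primitive endoderm genes had 2 of 9 lower (3 adjusted over the list alone, camera adjusted p = 0.189), ion and water transport 2 of 16 lower (3 adjusted over the list alone, 0.971), interferon response 1 of 8 lower (1 adjusted over the list alone, 0.998) and sterol biosynthesis 1 of 21 higher (2 higher and 1 lower adjusted over the list alone, 0.376). Oxidative phosphorylation had 1 of 79 lower (0 adjusted over the list alone, 0.655). Among 2-cell-stage transcripts (0.142, and 0.011 without Klf5 knockdown replicate 1, against an adjusted p = 0.81 with an estimated correlation), oocyte-inherited transcripts (0.585), glycolysis (0.998), cell cycle and mitosis (0.181), cumulus and granulosa cells (0.826) and the AP-2 family (0.826), 0 genes passed limma either way. The median and mean fold change differed in sign for ion and water transport (0.04 and -0.05) and for oxidative phosphorylation (0.01 and -0.01).

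The comparison of the Tfap2c knockdown with control asks which 8-cell transcripts depend on Tfap2c. Among the largest falls were Smpdl3a, a phosphodiesterase related to acid sphingomyelinase, with a log2 fold change of -4.37 (adjusted p = 1.3e-06), Tfeb, a transcription factor of lysosomal genes (-3.54, adjusted p = 2.1e-07), the transcription factor Sox21 (-3.43), the surface protein Ly6a (-3.40), Arpc1b (-3.34), Aqp3, a channel for water and glycerol (-3.21) and Ckb, a creatine kinase (-3.14). Among the largest rises were Amotl1, a member of the angiomotin family of the Hippo pathway (3.50, adjusted p = 2.6e-06), Scd2, a fatty acid desaturase (2.61), Mir682 (2.18), LOC664787 (1.98), B4galt6, an enzyme of glycosphingolipid synthesis (1.98), Il17rd, a regulator of FGF signalling (1.96) and the scavenger receptor Scarf1 (1.87). By limma 2749 of 11195 genes changed, 1416 up and 1333 down, and with libraries centred on their medians 1301 up and 1384 down, so the side with more genes turned. As deposited, 553 changed at least 2-fold, 173 up and 380 down. The count was 1542 without Tfap2c knockdown replicate 1, 1712 without replicate 2, 1620 without control replicate 1 and 1766 without control replicate 2, and in these 4 fits, too, fewer genes were up than down (692 and 850, 816 and 896, 756 and 864, and 856 and 910). Of the 76 named genes called here 64 kept their call without each library in turn. Mir682 did not: its log2 fold change was 1.94 without Tfap2c knockdown replicate 1 (adjusted p = 0.16), 2.42 without replicate 2 (0.083) and 1.20 without control replicate 2 (0.21), where it missed the threshold.

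Genes of both early lineages fell in the Tfap2c knockdown. Of 25 pluripotency and inner cell mass genes 16 fell and 2 rose (17 and 2 adjusted over the list alone), among them Tdgf1 (-2.82), Tfcp2l1 (-2.02), Pou5f1, the Oct4 gene (-1.47) and Klf4 (-1.09). The camera adjusted p was 4.0e-06, and the adjusted p = 0.050 with an estimated correlation. Of 19 trophectoderm genes 10 fell and 2 rose, the same numbers adjusted over the list alone, with Cldn4, a tight junction claudin, at -3.12, the FGF receptor Fgfr2 at -2.05, the glucose transporter Slc2a3 at -1.19 and Tead4, a partner of the Hippo effector Yap, at -0.80. For this list camera gave an adjusted p of 8.1e-05, and the adjusted p = 0.16 with an estimated correlation. In the list of the Arp2/3 complex and actin regulation 9 of 29 fell and 0 rose, the same numbers adjusted over the list alone. Arpc1b led this list, and Actb (-0.79), Tmsb10 (-1.11) and vinculin, Vcl (-1.10), followed. The list's camera adjusted p was 0.012, and the adjusted p = 0.16 with an estimated correlation. Of 26 cell polarity and junction genes 10 fell and 1 rose (12 and 1 adjusted over the list alone), with Cgn at -0.60 and Pard6b at -0.92. By camera the list's adjusted p was 0.0050, and the adjusted p = 0.35 with an estimated correlation. In the Klf family, which shares Klf2, Klf4 and Klf17 with the pluripotency list, 5 of 12 fell and 1 rose (5 and 2 adjusted over the list alone), with Klf10 at -1.91 and Klf17 at 1.11. For this list camera gave an adjusted p of 0.034, and the adjusted p = 0.39 with an estimated correlation. This call was lost without Tfap2c knockdown replicate 2 (adjusted p = 0.071) and without control replicate 1 (adjusted p = 0.053). Of 64 replication-dependent histone genes 17 fell and 1 rose (20 and 1 adjusted over the list alone), such as Hist1h1d at -0.56 and Hist1h4i at -0.62. The list's camera adjusted p was 2.9e-06, and the adjusted p = 0.46 with an estimated correlation.

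The p53 response moved the other way. In this list 17 of 26 genes rose and 2 fell (18 and 2 adjusted over the list alone), among them Trp53inp1 (1.45), the cyclin Ccng1, the kinase Plk2 (1.18) and Apaf1, which assembles the apoptosome (0.95). The camera adjusted p was 5.2e-06, and the adjusted p = 0.26 with an estimated correlation. The other lists did not pass, and some of them held genes changed in both directions. In the Hippo pathway 5 of 23 rose and 2 fell, the same numbers adjusted over the list alone, with Amotl1 and Ctgf (1.53) up and Amot down (-2.49), and the median (-0.05) and mean (0.13) differed in sign (camera adjusted p = 0.898). In sterol biosynthesis 7 of 21 rose and 2 fell, the same numbers adjusted over the list alone, with Fdps, which makes farnesyl diphosphate, at 1.01 and Dhcr7 at 1.14 (0.0817, passing without Tfap2c knockdown replicate 1, without control replicate 1 and with the filter at 5 linear units, lowest 0.016, against an adjusted p = 0.46 with an estimated correlation). In glycolysis 1 of 17 rose and 3 fell (5 and 4 adjusted over the list alone), with the hexokinases Hk2 at -1.52 and Hk1 at -1.28, and the median (0.10) and mean (-0.04) differed in sign (0.898). Heat shock and integrated stress response had 7 of 24 higher and 3 lower (9 and 4 adjusted over the list alone), with Ddit4 at 1.28, Hspa1a at 1.17 and Bag3 at 0.74 (0.175). Cell cycle and mitosis had 5 of 34 higher and 9 lower (6 and 10 adjusted over the list alone), with the kinetochore motor Cenpe at -1.97 and the phosphatase Cdc25a at -0.72 (0.338). Ion and water transport had 1 of 16 higher and 4 lower (1 and 5 adjusted over the list alone), with Aqp3 down and Aqp11 up at 1.18 (0.0977, passing at 0.039 with the filter at 5 linear units, against an adjusted p = 0.46 with an estimated correlation). Primitive endoderm had 3 of 9 lower, the same number adjusted over the list alone, with Gata6 at -0.58 (0.110). The interferon response had 1 of 8 higher and 2 lower (4 and 3 adjusted over the list alone), with Oasl2 at -1.36 and Irf9 at -1.48, and its median (0.43) and mean (-0.09) differed in sign (0.964). Oxidative phosphorylation had 5 of 79 higher and 3 lower (2 and 1 adjusted over the list alone), with Cycs, cytochrome c, at 0.59 (0.441). The 2-cell-stage transcripts had 3 of 16 higher and 2 lower (4 and 2 adjusted over the list alone, 0.898), ribosomal proteins 1 of 86 higher and 1 lower (0 adjusted over the list alone, 0.739) and the AP-2 family Tfap2c alone of 3 lower (0.0977). Among oocyte-inherited transcripts (0.918) and cumulus and granulosa cell genes (0.898) 0 passed limma. The genes named with values in this paragraph kept their calls without each library in turn.

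**Figure D2:**
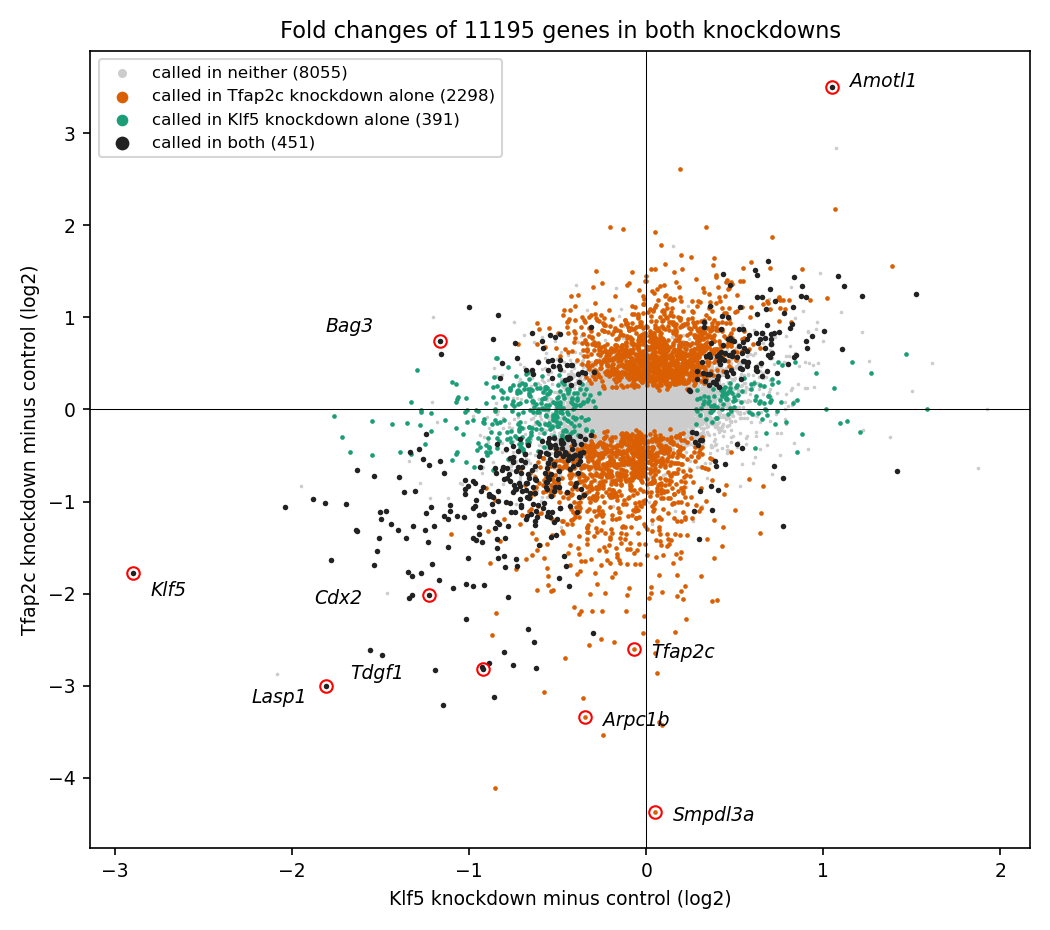
Log2 fold changes of 11195 genes against control in the Klf5 knockdown (horizontal axis) and the Tfap2c knockdown (vertical axis), coloured by the comparisons in which limma called them. Among genes called in both, 268 were lower in both, 121 higher in both and 62 opposite, and some of the named genes are circled.

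The knockdowns share 2 control libraries, so chance overlap is given for their calls, and simulated unchanged groups with the same controls for the correlation of their fold changes. In both knockdowns Lasp1 fell (-1.81 with Klf5 and -3.01 with Tfap2c knockdown), as did Grb7 (-1.56 and -2.61), the actin-associated Tagln2 (-1.49 and -2.67) and Tfcp2l1, and Cited2 rose (0.88 and 1.34). In all, 268 genes were lower in both and 121 higher in both, where independent calls would give 70.3 and 31.9. Another 62 genes were called in opposite directions, among them Bag3 (-1.16 and 0.74), the smooth muscle leiomodin Lmod1 (down and up), the laminin Lamb2 (-0.84 and 1.02) and Spred1, an inhibitor of Ras signalling (0.77 and -1.26). Lmod1, Lamb2, Spred1 and Tagln2 were chosen after their values were seen. Klf5 is among the genes lower in both, as it also fell in the Tfap2c knockdown (-1.78). Whether other shared changes follow from the lower Klf5 there was not tested. The overlap rests on the 842 calls of the Klf5 knockdown, a count that depended on each library, and it was not recounted with a library left out. The fold changes correlated across genes with r = 0.385, below the 0.496 that shared controls alone gave in simulation, while their covariance was 0.0609 against 0.0174 in simulation. The simulated groups held no changed genes, and real changes add spread that can lower r even where they agree. An r below the simulated one therefore does not decide on agreement. Genes are not independent replicates.

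Set against each other, the Tfap2c and the Klf5 knockdown differed in 2865 genes by limma, 1693 higher and 1172 lower with Tfap2c knockdown. Among the higher were Amotl1 (2.45), Scd2 (2.42), B4galt6 (2.18), Lmod1 (2.11) and Il17rd (2.09), and among the lower Smpdl3a (-4.42), Sox21 (-3.52), Ly6a (-3.47) and Tfeb (-3.29), with adjusted p from 5.0e-07 to 2.2e-05. These genes kept their call without each library in turn. Of the 268 genes lower in both knockdowns, 99 differed between them, 78 with the larger fall after Tfap2c and 21 after Klf5 knockdown. Of the 121 higher in both, 24 differed, 23 with the larger rise after Tfap2c knockdown. At least 2-fold differences numbered 492. The count of 2865 became 1599 without Tfap2c knockdown replicate 1, 1670 without replicate 2, 1767 without Klf5 knockdown replicate 1 and 1787 without replicate 2. The share of higher genes moved from 59.1% to 46.5% when libraries were centred on their medians (1279 up, 1472 down), so the side with more genes changed with the scaling.

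The motif knockouts ask what Tfap2c motifs contribute to Cdx2 and Arpc1b expression. Cdx2 fell in both: in the Arpc1bE_CdxE1 knockout it stood at 1.15 ± 0.53 (SD, n = 2) and in the CdxE2 knockout at 0.87 ± 0.08, against 2.41 ± 0.09 in control. The log2 fold changes were -1.26 (SE 0.25, adjusted p = 0.018) and -1.54 (SE 0.25, adjusted p = 0.0081). Arpc1b fell in the Arpc1bE_CdxE1 knockout, to 3.29 ± 0.02 (log2 fold change -1.31, SE 0.12, adjusted p = 0.0020), and differed from control by 0.16 in the CdxE2 knockout (adjusted p = 0.35), a sign that turned to -0.17 with median-centred libraries. Klf5 differed by -0.11 and -0.13 (adjusted p = 0.43 and 0.33) and Tfap2c by -0.03 and -0.07 (adjusted p = 0.82 and 0.61); with centred libraries Klf5 stood at -0.43 (adjusted p = 0.072) and, called lower, at -0.46 (0.044), and Tfap2c at -0.35 (0.11) and -0.40 (0.062). Mtif3, chosen as a neighbour of Cdx2, fell in the Arpc1bE_CdxE1 knockout (-0.66, adjusted p = 0.015). In the CdxE2 knockout it differed by -0.33 (adjusted p = 0.083). With centred libraries Mtif3 lay at -0.98 in the Arpc1bE_CdxE1 and at -0.66 in the CdxE2 knockout. The other tested neighbours of Cdx2, Lnx2, Polr1d, Pan3 and Pomp, had adjusted p of 0.25, 0.82, 0.090 and 0.78 in the Arpc1bE_CdxE1 knockout. Their values with centred libraries there were -0.57, -0.28, -0.60 and -0.26. In the CdxE2 knockout the neighbours of Arpc1b called were Arpc1a (0.39, adjusted p = 0.026) and Pdap1 (0.48, adjusted p = 0.017), both higher. With centred libraries neither was (0.06 and 0.15). In the Arpc1bE_CdxE1 knockout none of the tested neighbours of Arpc1b was called as deposited. With centred libraries all of them lay below control there. The values were -0.22 for Smurf1, -0.61 for Arpc1a, -0.53 for Pdap1, -0.31 for Bud31, -0.63 for Ptcd1, -0.60 for Cpsf4 and -0.38 for Atp5j2. The 33 tested genes flanking the stretch from Arpc1b to Cdx2 had a centred median of -0.24 in this knockout. Lying below control was thus not particular to the neighbours of Arpc1b. The Cdx2 level is low, 4.10 and 4.57 linear units in the control libraries, where the added 1 of the scale makes changes look smaller. Its call in the Arpc1bE_CdxE1 knockout was lost without control replicate 1 (adjusted p = 0.083), without control replicate 2 (0.11) and without the filter on low values (0.065), over alternatives from 0.0045 to 0.11. In the CdxE2 knockout it was lost without CdxE2 replicate 2 (0.0503), control replicate 1 (0.052) and control replicate 2 (0.057), over alternatives from 0.0017 to 0.057. The Arpc1b call held without each library.

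**Figure D3:**
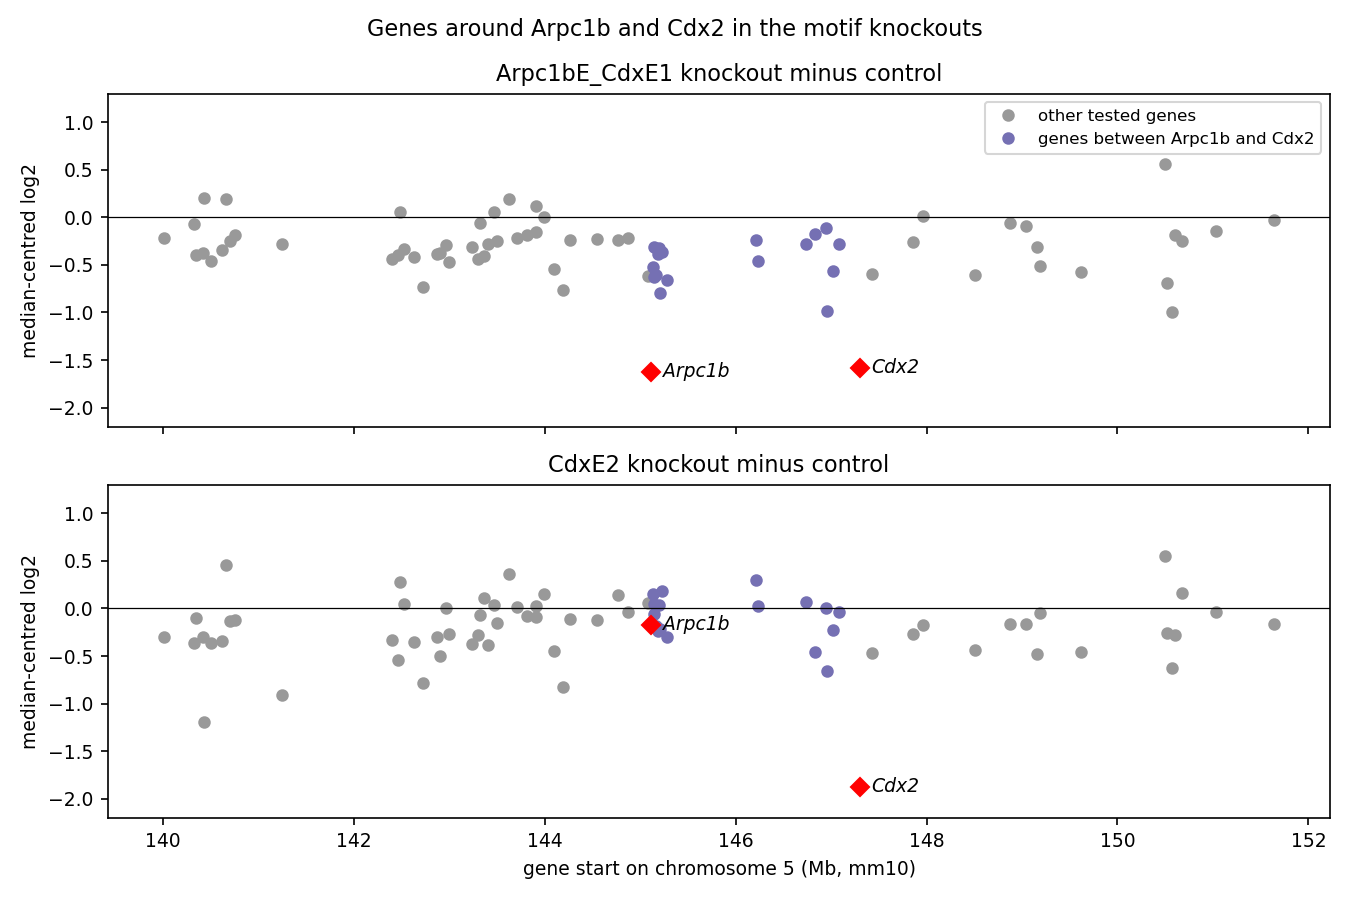
Log2 fold change against control with libraries centred on their medians, by gene start on chromosome 5, for tested genes around Arpc1b and Cdx2 in the Arpc1bE_CdxE1 (top) and CdxE2 (bottom) knockout, with n = 2 per group. Cdx2 lies at -1.59 and -1.87 and Arpc1b at -1.63 and -0.17, and the 17 genes between them have medians of -0.38 and -0.03.

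Both motif knockouts lay above control over most of the transcriptome. The median log2 fold change of all 10920 genes tested was 0.27 in the Arpc1bE_CdxE1 and 0.29 in the CdxE2 knockout, so changes are also given with each library centred on its median. Cdx2 then changed by -1.59 and -1.87 and Arpc1b in the Arpc1bE_CdxE1 knockout by -1.63. By limma 2621 genes changed in the Arpc1bE_CdxE1 knockout, 2532 up and 89 down, and 321 after centring, 178 up and 143 down. In the CdxE2 knockout 3270 changed, 3113 up and 157 down, and 681 after centring, 288 up and 393 down, so the side with more genes turned. The 4 motif knockout libraries stand apart from the other 6: 1 to 4 of their values lay between 0 and 0.001 linear units against 26 to 39, and 10466 to 10600 genes reached 1 unit against 9663 to 9917. The Arpc1bE_CdxE1 count was 1846 without its replicate 1, 2818 without replicate 2, 308 without control replicate 1 and 147 without control replicate 2. For CdxE2 it was 1047 without replicate 1, 477 without replicate 2, 629 without control replicate 1 and 681 without control replicate 2. Without the filter on low values the counts were 1166 and 1858, and 1729 genes were called for Arpc1bE_CdxE1 when only its own group and control were fitted. At least 2-fold changes numbered 268 and 296.

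**Figure D4:**
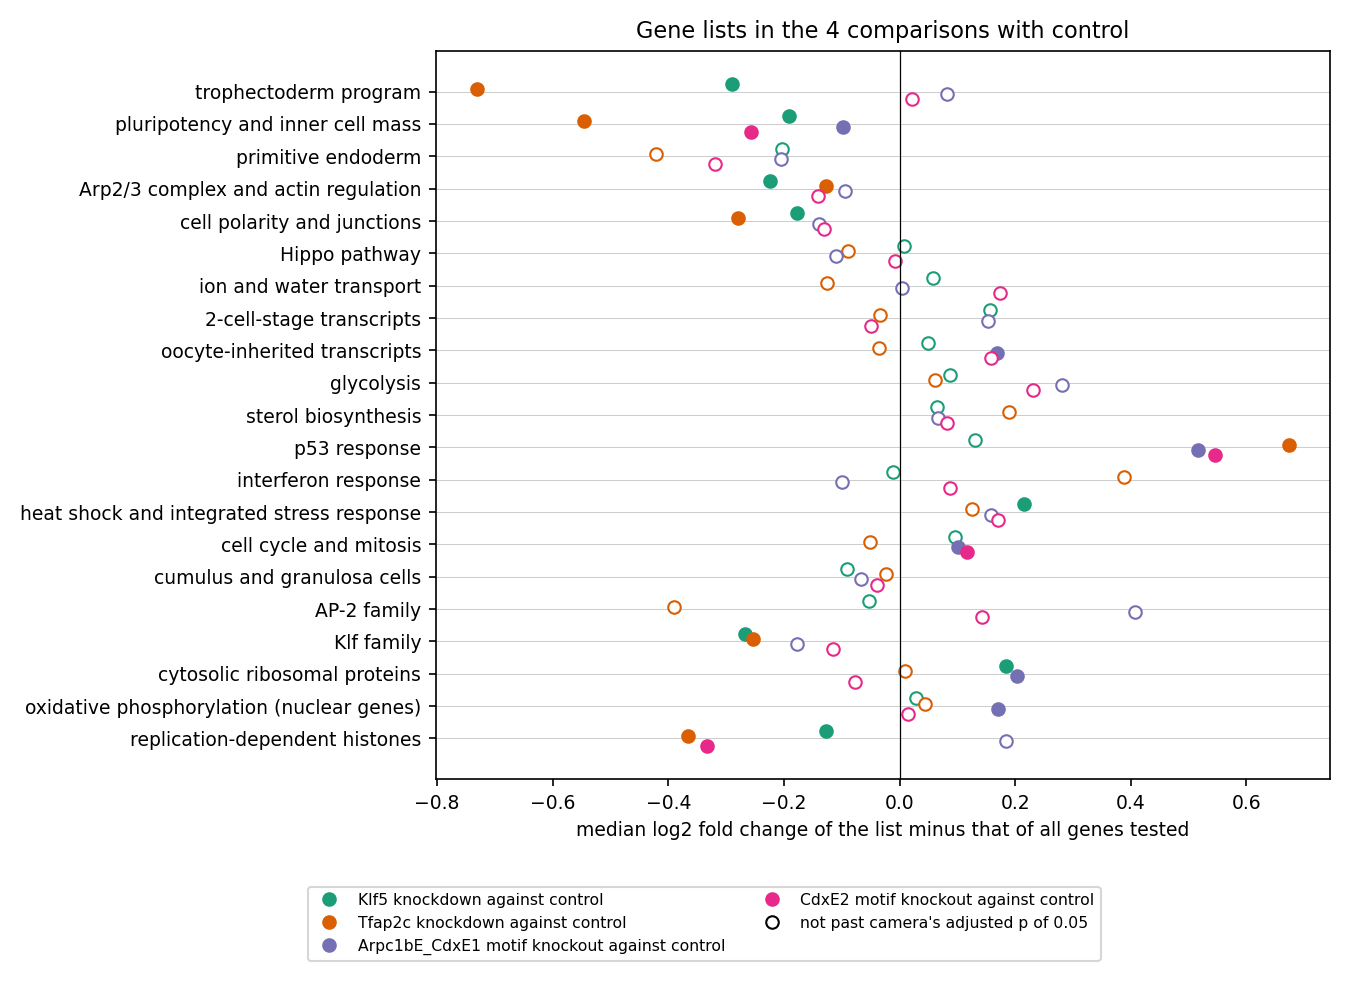
Median log2 fold change of each of the 21 tested gene lists minus the median of all genes tested, in the 4 comparisons with control; filled points passed camera at an adjusted p of 0.05 with the preset correlation. The p53 response lies above the median of all genes by 0.67 in the Tfap2c knockdown and by 0.52 and 0.55 in the motif knockouts, and the trophectoderm program below it by 0.73 in the Tfap2c knockdown.

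Small structured RNAs were among the largest rises in both motif knockouts. Snora26, a small nucleolar RNA that guides RNA modification, rose by 6.90 log2 units in the Arpc1bE_CdxE1 and by 6.68 in the CdxE2 knockout, Snord15b by 6.62 and 6.29, the vault RNA Vaultrc5 by 6.26 and 6.05, Snora15 by 6.01 and 5.60, Snora47 by 5.92 and 5.77, Snora21 by 5.26 and 5.03 and Snora24 by 4.90 and 5.24. Snora34 rose by 5.13 in the first and Tgoln2, a protein of the trans-Golgi network, by 4.87 in the second. For small nucleolar and Cajal body RNA genes, a class set after these values were seen and given no list test, 72 and 70 of 99 were called higher and 0 lower. Their medians were 1.42 and 1.27, against 0.27 and 0.29 for all genes, and with centred libraries 52 and 48 were higher and 0 lower. Rpl26, a ribosomal protein gene, changed by -5.54 and -5.78, Amd1, an enzyme of polyamine synthesis, by -3.45 and -3.57, and Oaz1, the antizyme that limits it, by -3.02 and -3.60. Snurf changed by -3.57 and -2.04 and Hnrnpa3, a splicing factor, by -1.56 and -2.38. Rpl37rt (-3.87), Dpm1-adnp (-2.10) and Wdr89 (-1.49) fell in the Arpc1bE_CdxE1 knockout, and Lpar1, a receptor of lysophosphatidic acid (-2.06), the nucleic acid binding protein Cnbp (-1.79) and Fam134c (-1.52) in the CdxE2 knockout. Centring ended the calls of Rpl37rt (adjusted p = 0.078) and of Snurf in the CdxE2 knockout (0.0597). In the Arpc1bE_CdxE1 knockout, Rpl37rt was called in none of the 4 fits without 1 library (adjusted p 0.069 to 0.14), Snurf and Oaz1 lost the call without 1 of them (highest 0.069 and 0.061) and Hnrnpa3 without control replicate 1 (0.14) and replicate 2 (0.12). The Hnrnpa3 value was -0.86 without Arpc1bE_CdxE1 replicate 2. In the CdxE2 knockout Hnrnpa3 lost it without CdxE2 replicate 2 (0.053) and control replicate 1 (0.055), and Snurf without CdxE2 replicate 2 (-1.27, 0.16) and control replicate 2 (-1.29, 0.19). These values come from the 4 libraries that stand apart in their lowest values. Whether reads of these genes are shared with copies or overlapping genes was not tested.

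In the Arpc1bE_CdxE1 knockout the p53 response rose with 23 of 26 genes and 0 fell (24 rose adjusted over the list alone), and 10 of them were still called higher with centred libraries. Centred values were 1.38 for Ccng1, 0.96 for Plk2, 0.86 for Zmat3 and 0.80 for Trp53inp1. By camera the list's adjusted p was 2.2e-08, and the adjusted p = 0.50 with an estimated correlation. Nuclear genes of oxidative phosphorylation rose in 37 and fell in 1 of 78 (46 and 1 adjusted over the list alone), of which 5 and 1 with centred libraries, among them Atp5k (1.23), Cox6b1 (0.97) and Ndufb9 (0.77). For this list camera gave an adjusted p of 0.0016, and the adjusted p = 0.72 with an estimated correlation. Cytosolic ribosomal proteins rose in 42 and fell in 2 of 86 (51 and 2 adjusted over the list alone), of which 2 and 2 with centred libraries, with Rps29 at 0.79 and Rpl26 at -5.86. The list's camera adjusted p was 0.0043, and the adjusted p = 0.72 with an estimated correlation. Cell cycle and mitosis genes rose in 19 of 34 (24 adjusted over the list alone) and 0 passed with centred libraries, where the camera adjusted p of 0.0016 became 0.18 (adjusted p = 0.50 with an estimated correlation). Oocyte-inherited transcripts rose in 11 of 30 (12 adjusted over the list alone) and 0 passed with centred libraries. By camera the list's adjusted p was 0.048, and the adjusted p = 0.72 with an estimated correlation. Pluripotency and inner cell mass genes lay below other genes by camera although their median was 0.18, since 8 of 25 rose and 2 fell (9 and 3 adjusted over the list alone), turning to 1 and 4 with centred libraries, where Dppa4 was the riser, at 0.57. For this list camera gave an adjusted p of 0.048, which became 0.21 with centred libraries, and the adjusted p = 0.50 with an estimated correlation. The ribosomal and oxidative phosphorylation calls were lost without Arpc1bE_CdxE1 replicate 1 (adjusted p = 0.14 for each) and the oocyte call without that library (0.73) and without control replicate 1 (0.13), while the pluripotency call was lost without each of the 4 libraries in turn (0.064 to 0.15). With the filter at 5 linear units the ribosomal (0.071) and oocyte (0.096) calls were lost, and with the replicate block the oocyte (0.056) and pluripotency (0.058) calls. All of these fold changes come from the libraries that stand apart in their lowest values. Fits without a library used deposited values, and calls with centred libraries were not refitted in that way. Of the 77 named genes called in this comparison 25 kept their call without each library in turn. Of the others, 11 lost it without Arpc1bE_CdxE1 replicate 1, 5 without replicate 2, 41 without control replicate 1 and 52 without control replicate 2. Cox6b1, Rps29 and Dppa4 were among the losers (highest adjusted p 0.051 for each).

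Other lists did not pass camera in the Arpc1bE_CdxE1 knockout. Histone genes rose in 29 and fell in 2 of 64 (31 and 2 adjusted over the list alone), of which 6 and 2 with centred libraries, among them Hist1h2ad (2.14), Hist2h2aa2 (1.83) and Hist1h3b (1.21), and the camera adjusted p was 0.106 (0.00017 without Arpc1bE_CdxE1 replicate 2 and 0.0048 with centred libraries, both above other genes, against an adjusted p = 0.79 with an estimated correlation). Heat shock and integrated stress response rose in 10 of 24 (14 higher and 1 lower adjusted over the list alone, 0.225) and, with centred libraries, in 1, Ddit4 (0.58), while 1 fell. Glycolysis rose in 6 of 17 (8 adjusted over the list alone, 0.362) and in 1 with centred libraries, the lactate transporter Slc16a1 (0.78). The trophectoderm program rose in 5 and fell in 1 of 19 (0.526), and with centred libraries Cdx2 alone was called, lower. In the actin list 4 of 29 rose and 1 fell (0.353), turning to 0 and 3 with centred libraries, where Arpc1b (-1.63), Arpc1a (-0.61) and Actg1 (-0.58) were lower; Arpc1a is named as a neighbour of Arpc1b. With deposited values 5 of 23 Hippo pathway genes rose (0.353), 5 of 16 of ion and water transport (0.353), 4 of 14 of the 2-cell-stage transcripts (0.884), 3 of 26 of polarity and junctions (0.353), 3 of 21 of sterol biosynthesis (0.231), 2 of 9 of primitive endoderm (0.353), and 1 each of the Klf family (0.0537), interferon response (0.526), AP-2 family (2 adjusted over the list alone, 0.881) and cumulus and granulosa cell genes (0.942). The polarity list passed with centred libraries (0.0499), below other genes, and so did the Klf family (0.0499), which also passed below other genes without Arpc1bE_CdxE1 replicate 2 (0.0099) and without control replicate 2 (0.023). With the filter at 5 linear units the Hippo pathway (0.036) and the Klf family (0.019) passed below other genes, and with the replicate block histones passed above (0.024). As deposited, the polarity, Klf family and Hippo pathway lists had an adjusted p = 0.72, 0.69 and 0.72 with an estimated correlation. In these lists 0 genes were called higher by limma with centred libraries and 1 lower, of the Klf family, where 321 genes were called in all. The medians of the primitive endoderm, polarity, Hippo pathway and Klf family lists lay above 0 as deposited (0.07, 0.13, 0.16 and 0.10) and below the median of all genes, so their direction depends on the scaling.

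In the CdxE2 knockout the p53 response again rose in 23 of 26 genes and fell in 0 (24 adjusted over the list alone), 8 of them with centred libraries, where Plk2 stood at 0.99, the death receptor Tnfrsf10b at 0.66, Trp53inp1 at 0.62 and Apaf1 at 0.43. The list's camera adjusted p was 3.8e-07, and the adjusted p = 0.54 with an estimated correlation. Histone genes split evenly, 10 up and 10 down of 64, the same numbers adjusted over the list alone, and 3 up and 16 down with centred libraries. Hist1h2ao (-1.46) and Hist1h2ah (-1.30) fell and Hist1h2ad (1.67) and Hist2h2aa2 (1.61) rose, with a median of -0.04 and a mean of 0.02 before centring (camera adjusted p = 4.0e-09, down, and adjusted p = 0.58 with an estimated correlation). Pluripotency and inner cell mass genes lay lower by camera, with 6 of 25 up and 3 down (7 and 3 adjusted over the list alone), turning to 1 and 6 with centred libraries, among them Tfcp2l1 (-1.45) and, as the riser, Klf17 (0.70). By camera the list's adjusted p was 0.0042, and the adjusted p = 0.35 with an estimated correlation. Cell cycle and mitosis genes rose in 25 of 34 (30 adjusted over the list alone) and in 1 with centred libraries, the phosphatase Cdc25a (0.53). For this list camera gave an adjusted p of 6.3e-05, and the adjusted p = 0.35 with an estimated correlation. These 4 list calls held without each library in turn. All of these values come from libraries that stand apart in their lowest values. Of the 78 named genes called in this comparison 40 kept their call without each library in turn. Of the others, 20 lost it without CdxE2 replicate 1, 35 without replicate 2, 26 without control replicate 1 and 33 without control replicate 2. Those named in this paragraph kept it with deposited values. Calls with centred libraries were not refitted with a library left out.

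Further lists in the CdxE2 knockout did not pass with deposited values. The trophectoderm program had 3 of 19 higher and 2 lower (0.153) and, with centred libraries, 2 higher and 3 lower: Hand1 at 0.51, Slc2a3 at 0.68, Cdx2, and Lrp2 at -1.08 among them. In the heat shock and integrated stress response 11 of 24 rose (12 adjusted over the list alone, 0.218), and with centred libraries 4 rose and 2 fell, with Ppp1r15a, a regulator of translation under stress, at 0.65, Ddit4 at 0.60, Hspa5 at 0.59 and Sesn2 at 0.58. Glycolysis had 8 of 17 higher (11 adjusted over the list alone, 0.125), turning to 2 higher and 1 lower centred, with Slc16a1 at 1.02. In the actin list 5 of 29 rose and 1 fell (0.497), turning to 1 and 2 centred, where Rdx, which links actin to the membrane, rose (0.46) and Actg1 was among the fallers (-0.81). Oxidative phosphorylation had 23 of 78 higher and 1 lower (24 and 1 adjusted over the list alone, 0.429), turning to 2 and 3 centred, with Atp5k at 1.00. Ribosomal proteins had 14 of 86 higher and 2 lower (12 and 2 adjusted over the list alone, 0.169), turning to 0 and 4 centred, with Rpl34 at -0.86. Oocyte-inherited transcripts had 13 of 30 higher (15 adjusted over the list alone, 0.0704), and Btg4, which promotes maternal RNA decay, stood at 0.59 centred. Ion and water transport had 7 of 16 higher (12 adjusted over the list alone, 0.0523), of which 1 centred, the Hippo pathway 7 of 23 (0.429), turning to 1 higher and 2 lower centred, with Cyr61 at 0.58, sterol biosynthesis 6 of 21 (7 adjusted over the list alone, 0.429), of which 0 centred, polarity and junctions 5 of 26 (1 adjusted over the list alone, 0.270), turning to 0 higher and 3 lower centred, and 2-cell-stage transcripts 3 of 14 (2 adjusted over the list alone, 0.429), turning to 1 higher and 2 lower centred, with Spz1 at 0.56. The Klf family had 3 of 12 higher (0.429) and, centred, 1 higher and 1 lower, primitive endoderm 2 of 9 (0.207) and 1 of each, and the interferon response 1 of 7 higher and 1 lower (0.717), and 0 and 1. The AP-2 family and cumulus and granulosa cells each had 1 of 3 higher (0.724) and 0 centred. With centred libraries 10 lists passed in all. Among them were actin and ribosomal proteins below other genes (adjusted p = 0.044 each), polarity and junctions below (0.024), glycolysis above (0.024), oocyte-inherited transcripts above (0.014) and ion and water transport above (0.044). With an estimated correlation, run on deposited values alone, these lists had adjusted p from 0.54 to 0.80. As deposited, the oocyte list passed without CdxE2 replicate 1 (0.024) and without control replicate 2 (0.032), glycolysis without CdxE2 replicate 1 (0.044) and ion and water transport without control replicate 2 (0.037), and ribosomal proteins passed below other genes with the filter at 5 linear units (0.020). Lrp2, Actg1 and Rpl34 lost their calls without at least 1 library (highest adjusted p 0.10, 0.066 and 0.060).

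Across the 4 comparisons with control camera with the preset correlation passed 8, 7, 6 and 4 of 21 lists, in the order Klf5 knockdown, Tfap2c knockdown, Arpc1bE_CdxE1 and CdxE2 knockout, and with an estimated correlation it passed 0 in each, with smallest adjusted p of 0.068, 0.050, 0.50 and 0.35. The estimated form rests on few residual degrees of freedom, so these misses do not decide whether gene correlation accounts for the list results. The fry test, which asks whether a list's own genes move one way on balance, passed 5, 12, 15 and 11. In both motif knockouts all lists it passed were up, which follows the shift of most genes, and they include pluripotency (0.0093 and 0.023), which camera put below other genes.

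Against each other, the motif knockouts differed by limma in 5 of 10920 genes, while 1238 had an unadjusted p under 0.05. Arpc1b was higher in the CdxE2 knockout by 1.46 (SE 0.12, adjusted p = 0.019), as was Lsm5, a component of the spliceosome's U6 particle, by 1.76 (SE 0.11, adjusted p = 0.0045), Dpm1-adnp, a symbol with no single GENCODE model, by 2.23 (SE 0.22, adjusted p = 0.042) and Dbf4, the activator of the replication kinase Cdc7, by 0.78 (SE 0.08, adjusted p = 0.042). Lpar1 was lower by 2.28 log2 units, a difference of -2.28 (SE 0.14, adjusted p = 0.0045). Lsm5 lies on chromosome 6 (56701063 to 56704710), Dbf4 on chromosome 5 (8396973 to 8422716) and Lpar1 on chromosome 4 (58435255 to 58553898). Cdx2 differed by -0.28 (adjusted p = 0.67). Without a library the count was 5 and 4 for CdxE2 replicates 1 and 2, and 17 and 150 for Arpc1bE_CdxE1 replicates 1 and 2. The Arpc1b call was lost without CdxE2 replicate 1 and without replicate 2 (highest adjusted p 0.080), and Dbf4 and Dpm1-adnp lost theirs in 2 and 1 of these fits (highest 0.39 and 0.0504), while Lsm5 and Lpar1 kept theirs. Other settings gave 0 genes without the filter on low values, 2 without the trend, 2 with these groups fitted alone, 3 with transcripts of at least 1000 bases and 14 in a joint fit of all groups.

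The knockouts share an upward shift of most genes, which bears on how their calls overlap. The overlaps that follow were counted on deposited values and not recounted with centred libraries. With centring 178 genes in all were higher in the Arpc1bE_CdxE1 and 288 in the CdxE2 knockout. Several of the counts of shared rises below exceed these. In both knockouts 1892 genes were higher, where independent calls would give 722, 56 lower and 0 opposite, with a covariance of fold changes of 0.139 against 0.0176 from shared controls in simulation. The Tfap2c knockdown and the Arpc1bE_CdxE1 knockout had 515 genes higher in both (317 for independent calls), 24 lower in both and 239 opposite, and the Tfap2c knockdown and the CdxE2 knockout 679 (390), 70 and 266. Independent calls leave out the shared controls, which alone gave r of 0.498 and 0.501 in simulation, above the 0.189 and 0.249 of these pairs, with covariances of 0.0389 and 0.0520 against 0.0176 in each. As for the knockdowns, an r below that of unchanged groups does not decide on agreement, here or for the pairs that follow. For the Klf5 knockdown the numbers were 140 (55.6), 12 and 83 with Arpc1bE_CdxE1 and 155 (68.4), 36 and 117 with CdxE2, with r of 0.263 and 0.279 against 0.498 and 0.499 in simulation and covariances of 0.0349 and 0.0375 against 0.0175 in each. The 2 control libraries serve every comparison and are too few to be divided, and knockdown values were compared with control values from another table.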

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

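The tests of scaling, of the control libraries, of separate quantification and of a chance run of neighbours were chosen after the results were seen. The tests against gene length, GC content and level, and of the whole interval, were set before theirs.

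The direct comparison of the motif knockouts singled out genes whose change from control differed between them. By limma these were Dpm1-adnp (2.23 log2 units higher in the CdxE2 knockout), Lsm5 (1.76 higher), Arpc1b (1.46 higher), Dbf4 (0.78 higher) and Lpar1 (-2.28, lower). For Arpc1b the change lies in the Arpc1bE_CdxE1 knockout, and for Lpar1 in the CdxE2 knockout, where it fell from 4.14 to 2.09 log2 units. Lsm5 stood at 3.57 in control, 3.72 in the Arpc1bE_CdxE1 and 5.49 in the CdxE2 knockout. Dpm1-adnp has no single gene model. The calls of Dpm1-adnp, Arpc1b and Dbf4 did not all hold with 1 library left out: each was lost in at least 1 such fit. Lsm5 and Lpar1 kept theirs.

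In both motif knockouts most called genes lay above control. Against the 4 knockdown libraries in place of control, 95.8% of the genes called the same way in both knockouts kept their direction in the Arpc1bE_CdxE1 and 96.9% in the CdxE2 knockout, which argues against control libraries out of line with the rest. After centring, 10.0% of the Arpc1bE_CdxE1 calls (262 genes) and 13.5% of the CdxE2 calls (443 genes) kept call and direction, but centring removes a common shift whatever its origin, so it does not decide on 1 scale factor per library. Libraries were also scaled to equal linear sums, Rn45s left out. The median log2 fold change of all genes then went from 0.27 to 0.0026 in Arpc1bE_CdxE1 and from 0.29 to 0.050 in CdxE2. The shift was thus close in size to the difference in sums, whose origin this scaling does not show. At most 4 values of a motif knockout library lay between 0 and 0.001 linear units, against 26 to 39 in the 6 others, so a separate quantification and an effect of the knockouts cannot be told apart. No biological explanation was tested.

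Genes between Arpc1b and Cdx2 lay lower in the Arpc1bE_CdxE1 than in the CdxE2 knockout. Of 17 genes 16 were higher in CdxE2, by a median of 0.36. By limma 0 passed the threshold and 9 had an unadjusted p under 0.05. Set against the mean of the other knockout, library medians were -0.26 and -0.52 for Arpc1bE_CdxE1 and 0.39 and 0.46 for CdxE2. These values show the same contrast from either side. Against control, the centred median of these genes was -0.03 in CdxE2. Of 10135 windows 36 had a median as far from 0, all of them below it, a window p of 0.00365 counting the interval itself. Each window shares all but 1 of its genes with the next, so a window p is not a share of independent runs. Medians of the other windows ran from -0.54 to 0.26, so runs farther from 0 occurred elsewhere, toward lower values in CdxE2. The window p measures spread over genes of 1 contrast and not between libraries. Within these limits the values argue against a chance run of this direction, and 0.38 was left after a fit on length, GC content and level. A change of the whole interval in the Arpc1bE_CdxE1 knockout stays open: the window p for a median as low against control was 0.000691, and 0.522 for CdxE2, yet against 33 flanking genes the one-sided permutation p was 0.0703 (medians -0.38 inside and -0.24 outside), while the direct difference gave 0.00522. The permutation treats neighbouring genes as independent, so its p does not measure spread between libraries. Arpc1a, among the flanking genes, moved like those inside (centred -0.61, direct difference 0.69). A change along the chromosome and an effect of the lost motifs on several neighbours cannot be told apart, since both knockouts have 2 libraries and the deletions' extents are not known here.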

How the results depend on the processing

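The equal-sum scaling, the limit on transcript length, the fits without motif knockout libraries, the joint fit of the knockouts and the centring of gene lists are tests chosen after the data were seen. Counts in order are Klf5 knockdown, Tfap2c knockdown, Arpc1bE_CdxE1 knockout, CdxE2 knockout, between the knockouts and Tfap2c against Klf5 knockdown, where the reported counts are 842, 2749, 2621, 3270, 5 and 2865. Asking for a 2-fold change left 116, 553, 268 and 296 genes in the comparisons with control and 492 between the knockdowns, which follows from the added condition. Leaving out each library in turn gave 211 to 317, 1542 to 1766, 147 to 2818, 477 to 1047, 4 to 150 and 1599 to 1787 genes, and the numbers of lists passing camera, 8, 7, 6 and 4 as reported, ranged over 8 to 9, 6 to 8, 2 to 7 and 4 to 6; the lone library left is assumed to vary like the other groups. With no filter on low values 507 genes were called in the Klf5 knockdown, 1166 and 1858 in the knockouts and 0 between them. For the Arpc1bE_CdxE1 knockout median centring gave 321 genes, quantile normalization 325, equal sums 295 and a fit of only the 2 groups 1729; for CdxE2 the first 3 gave 681, 659 and 692. Between the knockouts 2 genes were called without the trend, 2 with only the 2 groups, 3 with transcripts of 1000 bases or more and 14 in the joint fit. With an estimated correlation 0 lists passed in each of the 4 comparisons, and with centred libraries 10 passed in the CdxE2 knockout. Treating the replicate number as a replicate block gave 706, 2615, 2483, 3087, 4 and 2735 genes, and the replicate numbers did not pair the libraries (r of same-number deviations -0.05 to 0.04 over 10 pairs of groups). Directions turned in values near 0: Arpc1b in the CdxE2 knockout was -0.17 with centring, -0.18 with quantile normalization and -0.13 with equal sums; Ctnnb1 there was -0.00054 with centring; and Tfap2c was 0.0495 without Arpc1bE_CdxE1 replicate 1, over -0.11 to 0.0495 in that knockout with 1 library left out, and 0.00076 without CdxE2 replicate 2, over -0.13 to 0.00076 with 1 left out, while centring gave -0.35 and -0.40. For the 299 named results past the threshold, of 314, 4322 of 5008 values under alternatives kept direction and side of the threshold, 685 no longer passed and 1, that of Ctnnb1 above, turned. The cause was not tested except where named. The joint fit planned for tables with identical control columns was not run as planned, since control stands in 1 table, and depth could not be weighed without counts.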

Other observations

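The tests of scaling and of separate quantification below were chosen after the results were seen, and that of level, length and GC content before its result.

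Genes named here were chosen after their values were seen. Called higher in both knockdowns were Cebpd, a transcription factor of the C/EBP family (1.12 with Klf5 and 1.34 with Tfap2c knockdown), and Gclc, the first enzyme of glutathione synthesis (0.87 and 1.23). Lower in both were Cmip (-1.54 and -1.69), the metalloreductase Steap3 (-1.52 and -1.54) and Ahnak (-1.35 and -1.40). Called in opposite directions were Tcf23 (-0.86 and 0.77), Fbxo21 (0.77 and -0.75), the homeobox gene Nkx6-2 (1.41 and -0.67) and Phex, a membrane endopeptidase (-0.64 and 0.83). In that order their limma adjusted p was 0.019, 0.0075, 0.0042 and 0.040 in the Klf5 knockdown. In the Tfap2c knockdown it was 0.011, 0.0022, 0.033 and 0.0043. Some of these lie near the threshold, and the number of Klf5 knockdown calls depended on each library.

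The p53 response list lay above control in both motif knockouts. With centred libraries 10 members in the Arpc1bE_CdxE1 and 8 in the CdxE2 knockout were still called higher, which argues against 1 scale factor per library as the whole cause. The list's medians, 0.79 and 0.84, lay at percentile 100 of 10000 random lists matched on level, length and GC content, whose central 95% ran from 0.20 to 0.44 and from 0.20 to 0.47. Random lists treat genes as independent, and with the estimated correlation of 0.178 the list's camera adjusted p was 0.50 and 0.54. Separate quantification of the motif knockout libraries stays open for the knockouts, although 17 members were called higher in the Tfap2c knockdown, whose libraries resemble control in their lowest values (median 0.71, random lists -0.10 to 0.20). A response to handling or injection of the embryos was not tested, and the Klf5 knockdown median of 0.11 lay at percentile 98.5.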
